A study of Mus musculus with 6 samples.

How the data were processed

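Bulk RNA-seq was analysed from 6 libraries of mouse muscle stem cells, the resident stem cells of skeletal muscle, sorted from uninjured hindlimb muscle. Per the labels, both groups carried the Opa1/Pax7-CreERT2 design and received tamoxifen by gavage for 5 days, and cells were collected 3 days later. Animals without Cre form the WT group (n = 3 libraries) and animals with Cre form the KO group (n = 3 libraries). Sorting was for alpha-7 integrin and VCAM1 and against SCA1, CD45 and CD31, and RNA was taken from freshly isolated cells with a kit for small inputs. The groups differ in Cre as well as in Opa1, with no Cre-positive control. Nothing in the labels says how many animals went into a library, so p-values of single genes measure the spread between these libraries.

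The authors deposited whole-number read counts per gene, 1 file per library, with no normalization. Per the submitters' processing notes, the tools were Trim Galore 0.5.0, cutadapt 2.5, STAR 2.6.0c, HTSeq 0.6.1p2, edgeR and DESeq2 (the last pair without versions), and the build was GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Each file holds 49652 gene rows and 5 summary rows. The summary rows were left out of library sizes and tests. Reads without a feature made up 11.15% to 17.02% of all reads in the files, ambiguous reads 1.21% to 1.42% and reads that aligned more than once 14.82% to 24.57%. Because such reads are not counted, values of near-identical paralogs (globins, Gstm genes) are uncertain. The 9 small and ribosomal RNA classes miRNA, snRNA, snoRNA, rRNA, scaRNA, sRNA, scRNA, mitochondrial tRNA and mitochondrial rRNA have no gene rows and are not analysed here.

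Total gene counts were 56606886, 48329905 and 52951943 in WT replicates 1 to 3 and 50267675, 41410136 and 56591699 in KO replicates 1 to 3. Opa1 had 871 to 3856 counts per library, so the spread between libraries, not counting error, limits the precision. Gene symbols, biotypes and positions were taken from GENCODE M21, which is on GRCm38 too, by gene ID without its version. Of the 49652 gene rows, 49399 matched.

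Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. KO was compared with WT by the quasi-likelihood test of edgeR with robust estimation, TMM scaling, no covariate and the package's filter on low counts, which kept 18832 genes. P-values were adjusted by Benjamini-Hochberg over those genes and a gene was called at an adjusted p under 0.05. Fold changes are log2, KO minus WT, with a prior count of 0.125. Standard errors are the absolute log2 fold change divided by the square root of F. Normalised read counts are given as CPM after TMM scaling. For gene lists, limma's camera was run on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. With the preset correlation it sets the genes of a list against all other genes. Its p-values then do not measure the spread between libraries. Adjustment was over 25 pathway lists and, separately, over 8 marker lists of other cell types. A further list of sex-linked genes is given as values only. The same test with an estimated correlation and limma's fry were run beside it. Both take the spread between libraries into account, so they differ from the preset run in more than the correlation. Opa1 also had an exact permutation test on the same log2 CPM.

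Groups, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names Opa1, up to 12 called genes per direction with a mean log2 CPM of at least 1 and groups that do not overlap, up to 4 called members of each pathway list or the 2 members with the smallest p where none was called, the 2 most abundant members of each marker list, and 12 gate and state genes. As edgeR called no gene, the 8 genes per direction with the smallest p that met the other conditions are also named, a choice made after their values were seen. So are Arntl, Cry1, Fos, Mdm2, Mfn1, Mfn2, Dnm1l, Mki67, Klhdc7a, Colgalt2 and Syt14, which the rule does not name.

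The scripts were tested on simulated counts with the means and depths of the 18832 genes in KO against WT. With dispersions as estimated per gene, 16% of genes changed by 2-fold and 64% of those changed by 4-fold were called, with 5 false calls. With a dispersion of 0.05 these shares were 56% and 100%, with 7 false calls. A shifted list was called and 0 of the other lists were. The simulated genes varied independently and the lists were random genes, so this does not test false calls of lists with correlated members. Differences between libraries shared by many genes were not simulated either, so the shares of genes called need not hold for the real libraries. Estimated correlations in the real lists were, for example, 0.04 for p53 targets, 0.61 for interferon response and 0.81 for cell cycle genes. The alternatives were DESeq2, limma voom, 3 other scalings, 2 other filters, non-robust estimation, the replicate number as a block, GC offsets with and without that block, thinning to the smallest total, protein-coding nuclear genes only, lists without shared members, and each library left out. A surrogate variable and a Y-linked covariate were added after the data were seen.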

Results

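The series asks how loss of OPA1, a dynamin-like GTPase that fuses the inner mitochondrial membrane and shapes its cristae, alters gene expression in quiescent muscle stem cells. It holds 1 comparison, KO (Cre-positive, n = 3 libraries) against WT (Cre-negative, n = 3 libraries), in freshly sorted, uninjured cells. Between 41410136 and 56606886 reads per library were counted in genes, and 23812 to 24848 genes had at least 1 count.

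Opa1 transcripts were lower on average in KO, at 26.3 ± 8.5 CPM (SD, n = 3) against 56.1 ± 21.4 CPM (SD, n = 3) in WT, or 46.9% of the WT mean. The gene lies on chromosome 16 from 29579334 to 29654884 on the plus strand of GRCm38 (ENSMUSG00000038084.16). Single WT libraries had 68.2, 31.4 and 68.8 CPM (raw counts 3856, 1504 and 3677), and single KO libraries 17.5, 34.4 and 27.1 CPM (raw counts 871, 1426 and 1539). WT replicate 2 thus lay inside the KO range, against its label, and is called the library labelled WT replicate 2. The log2 fold change was -1.09 (SE 0.37, 95% interval -1.97 to -0.22). In edgeR's quasi-likelihood test its unadjusted p was 0.0215 and its adjusted p 0.99998, so Opa1 did not pass over all genes. The exact two-sided permutation test on log2 CPM gave p = 0.2, where 3 against 3 libraries cannot go below 0.1. Without the library labelled WT replicate 2 the log2 fold change was -1.38, and KO stood at 38.5% of the other 2 WT libraries. Counts are per gene, so reads from exons outside the deleted part still count toward Opa1.

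**Figure D1:**
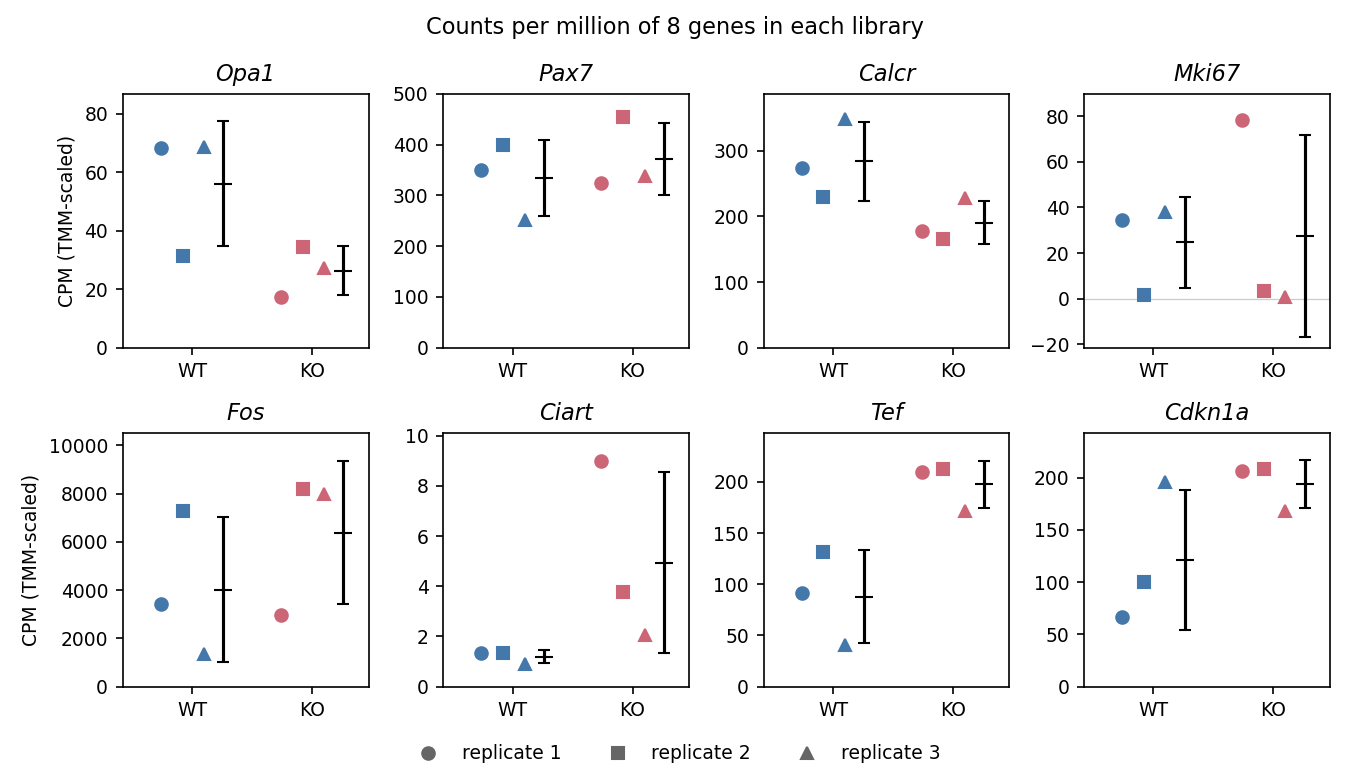
TMM-scaled CPM (vertical axes, starting at or below 0) of 8 genes in the 3 WT and 3 KO libraries, with symbols for the replicate number, and the mean ± SD of each group beside the points. For Opa1 the library labelled WT replicate 2 (31.4 CPM) sits between the KO libraries, whereas Tef is higher in each KO library than in any WT library and Mki67 differs widely within both genotypes.

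Single genes with the clearest separation of the groups were chosen after their values were seen, and none of them passed edgeR's adjusted threshold. Higher in every KO library were Mcc, a negative regulator of Wnt signalling and cell cycle entry (82.8 ± 9.23 against 38.8 ± 7.4 CPM, log2 fold change 1.09, SE 0.19), and Snai1, a transcriptional repressor of the epithelial program (7.49 ± 0.859 against 2.46 ± 0.538 CPM, 1.60, SE 0.34). Enpp1, an ectoenzyme that makes pyrophosphate, had a log2 fold change of 1.56 (SE 0.33). Slc2a1, the basal glucose transporter, stood at 29.6 ± 3.47 against 18.6 ± 1.16 CPM. Trim21, Usp37, Tob2 and Phf13 had log2 fold changes of 1.32, 0.41, 0.43 and 0.67. Lower in every KO library were Mrln, which encodes the micropeptide myoregulin that inhibits the sarcoplasmic calcium pump (19.0 ± 7.66 against 81.2 ± 35.8 CPM, -2.09, SE 0.44), and Plat, the tissue plasminogen activator (29.4 ± 12.1 against 90.2 ± 28.7 CPM, -1.62, SE 0.35). Tshr, the thyrotropin receptor, had -1.55 (SE 0.37), the matricellular gene Postn -1.89 (SE 0.45) and Plbd1 -1.12 (SE 0.20). Tnfrsf19, Gstm7 and Anxa5 had -0.78, -1.39 and -0.51. These means include the library labelled WT replicate 2.

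Over all 18832 genes, edgeR's quasi-likelihood test called 0 genes, with 393 at an unadjusted p under 0.05 (204 higher and 189 lower in KO), or 2.09%. That is below the share of 0.05 that chance alone would give, so their number is no sign of a genotype difference. A division of the libraries across genotype, as described below, can lower this share. It therefore does not argue against a difference either. DESeq2 called 20, 11 higher and 9 lower, and limma voom called 0. Of the 20, 10 had a mean log2 CPM under 1 and 6 were at 0 in a whole group. Among those named above, DESeq2 called Mcc (adjusted p 0.00355), Snai1 and Enpp1 (both 0.0103) as higher, and Mrln and Plbd1 (both 0.00324), Tnfrsf19 (0.00421), Plat (0.0103), Gstm7 (0.0204) and Tshr (0.0438) as lower. The 3 KO libraries lay wholly on 1 side of the 3 WT libraries for 1233 genes (6.55%), where chance gives 10%. Such a division can lower this share as well. The biological coefficient of variation was 0.52, and log2 CPM profiles correlated across genes at 0.911 to 0.937 within WT, 0.920 to 0.934 within KO and 0.916 to 0.957 between them.

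Genes that mark the quiescent state and the sort gate did not pass the test. The quiescence list (41 measured genes, 20 positive and 21 negative log2 fold changes, 0 called over all genes and 0 adjusted over the list alone) was not called by limma camera (adjusted p 0.404). Calcr, the calcitonin receptor that holds muscle stem cells quiescent, stood at 190 ± 33.1 against 284 ± 60.6 CPM (log2 fold change -0.58, SE 0.20), and Col5a1, a collagen V chain of their niche, at 30.2 ± 6.56 against 59.0 ± 24.5 CPM (-0.97, SE 0.32, and -0.58 without WT replicate 3). Neither passed. Pax7, the transcription factor that defines these cells, was at 372 ± 70.7 CPM in KO and 334 ± 74.5 in WT. Log2 fold changes were -0.11 for Spry1, -0.15 for Cd34, -0.30 for Myf5, 0.33 for Myod1 and 0.07 for Myog, with standard errors up to 1.16. With a library left out they ranged from -0.26 to 0.10, -0.26 to -0.03, -0.48 to -0.15, -0.04 to 0.83 and -2.12 to 0.62, in that order. Without KO replicate 1, Spry1 turned to 0.10, Cd34 moved to -0.03, Myf5 to -0.15, Myod1 to -0.04 and Myog to -2.12. The gate genes Vcam1 and Itga7 had -0.02 and 0.14. The Notch list (adjusted p 0.19) and the myogenic commitment list (0.858), with Tnnt1 at -0.56, were not called either. All of these lists had 0 members called over all genes and 0 adjusted over the list alone.

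Circadian clock genes rose as a list with the preset correlation, with 14 of 18 members positive and a median log2 fold change of 0.62 (limma camera, adjusted p 0.000526). The list's mean log2 CPM was 5.00, 5.77 and 5.02 in WT and 5.46, 6.11 and 5.88 in KO. WT replicates 1 and 3 and KO replicate 1 thus lay below the other libraries, and the library labelled WT replicate 2 lay above KO replicate 1. The list's adjusted p was 0.983 with an estimated correlation, so the call was lost. Ciart, a clock repressor, stood at 4.93 ± 3.6 against 1.20 ± 0.261 CPM (log2 fold change 2.04, and 1.28 without KO replicate 1), and Tef, a clock output factor, at 198 ± 23 against 87.8 ± 45.4 CPM. Arntl, the core activator that works with Clock, went the other way, at 10.7 ± 7.84 against 43.9 ± 23 CPM (log2 fold change -2.03, SE 0.80). No member was called over all genes, and 0 were called adjusted over the list alone. Without WT replicate 1 the list's adjusted p was 0.0935.

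p53 target genes also rose as a list with the preset correlation, with 21 of 25 members positive and a median of 0.30 (adjusted p 0.00506, and adjusted p 0.983 with an estimated correlation). The list's unadjusted p was 0.0478 by camera with an estimated correlation and 0.047 by fry. Each was the smallest of the 25 lists, and neither passed after adjustment. Its mean log2 CPM was 4.46, 4.50 and 4.62 in WT and 5.13, 4.87 and 4.66 in KO. Ccng1 stood at 97.0 ± 19.2 against 72.5 ± 7 CPM and Phlda3, an inhibitor of Akt, at 188 ± 67 against 124 ± 33 CPM. Mdm2, the ubiquitin ligase of p53, had a log2 fold change of 0.28 (SE 0.14) and Cdkn1a, the cell cycle inhibitor p21, 0.68 (SE 0.37). Cdkn1a moved to 0.39 without WT replicate 1 and to 1.22 without WT replicate 3, and Phlda3 and Ccng1 moved from 0.60 and 0.42, each to 0.27, without KO replicate 1. There were 0 calls over all genes and 0 adjusted over the list alone. The list's adjusted p was 0.158 without WT replicate 1 and 0.103 without KO replicate 1.

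Immediate early and early activation genes rose as a list with the preset correlation (27 of 35 members positive, median 0.36, adjusted p 0.00519, and adjusted p 0.998 with an estimated correlation). Its mean log2 CPM was 5.87, 6.91 and 5.27 in WT and 5.65, 6.92 and 6.98 in KO, so WT replicates 1 and 3 and KO replicate 1 lay below the other 3 libraries, the reverse of cell cycle genes. The share of reads without a feature divided the libraries alike, at 11.15%, 16.27% and 14.64% in WT and 11.57%, 15.45% and 17.02% in KO. Fos was at 3440, 7266 and 1365 CPM in WT and 2970, 8189 and 7987 CPM in KO, so for this gene the library labelled WT replicate 2 lay nearest to KO replicates 2 and 3. Its log2 fold change of 0.67 (SE 0.62) ranged from 0.25 to 1.41 with a library left out. Id1 had a log2 fold change of 0.85 (SE 0.33) and Gadd45b 0.70 (SE 0.37, and 0.45 without WT replicate 3). The call was lost without WT replicate 1 (0.246), WT replicate 3 (0.632), KO replicate 2 (0.233) or KO replicate 3 (0.418).

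Interferon response genes rose as a list with the preset correlation (29 of 33 members positive, median 0.19, adjusted p 0.00624, and adjusted p 0.998 with an estimated correlation). WT replicate 3 had the lowest mean log2 CPM, 3.42 against 4.29 to 4.83 in the other libraries. Bst2 was at 50.0 ± 5.37 against 36.4 ± 13 CPM (log2 fold change 0.46, and 0.19 without WT replicate 3) and Xaf1 had a log2 fold change of 0.29 (SE 0.17). Without WT replicate 3 the direction turned (adjusted p 0.632), and without KO replicate 1 or 3 the adjusted p was 0.0667 or 0.368. Endothelial markers were also lowest in WT replicate 3, at a mean log2 CPM of 0.66 against 2.02 to 3.64 elsewhere.

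Nuclear-encoded respiratory chain subunits fell as a list with the preset correlation, by a small amount (65 of 77 members negative, median -0.07, adjusted p 0.00624, and adjusted p 0.998 with an estimated correlation). Its mean log2 CPM was 7.55, 7.37 and 7.46 in WT and 7.62, 7.26 and 7.25 in KO, so KO replicate 1 was the highest of the 6 libraries, against the direction of the list, followed by WT replicates 1 and 3, as for cell cycle genes. Ndufa2 stood at 174 ± 10.3 against 201 ± 9.54 CPM and Ndufs4 at 53 ± 3.34 against 61.4 ± 3.92 CPM. The call was lost without WT replicate 1 (0.453), WT replicate 3 (0.108), KO replicate 2 (0.347) or KO replicate 3 (0.768), and with a surrogate variable added after the data were seen (0.239). For this list and the immediate early and interferon lists, 0 members were called over all genes and 0 adjusted over the list alone.

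Other mitochondrial and stress lists were not called with all 6 libraries and no covariate. The list of mitochondrial fusion, fission and cristae genes without Opa1 had 13 positive and 11 negative members (median 0.01, adjusted p 0.956), and log2 fold changes were 0.06 for Mfn1 (SE 0.27), -0.07 for Mfn2 (SE 0.26) and 0.02 for Dnm1l (SE 0.23). Mief2 had -0.97 (SE 0.45), and -1.53 without KO replicate 1. Mitochondrially encoded mRNAs had a median of -0.10 (adjusted p 0.858, and called lower in KO with the surrogate variable at 0.045), with mt-Co1 at 3699 ± 890 against 4429 ± 1312 CPM (log2 fold change -0.26, from -0.43 to 0 with a library left out). Their mean log2 CPM was 6.93, 7.59 and 6.89 in WT and 6.73, 7.37 and 7.21 in KO. Adjusted p was 0.786 for mitochondrial chaperones and proteases, 0.864 for mitochondrial biogenesis, 0.998 for mitophagy, autophagy and lysosome, and 0.119 for fatty acid oxidation and the TCA cycle. For the integrated stress response downstream of ATF4 it was 0.858, with Mthfd1l at 0.83 (SE 0.30), and for glutathione and antioxidant defence 0.864. The glutathione list had a median of 0.02, a mean of -0.02 and a test direction down. Glycolysis (0.956) had a median of -0.04 and a test direction up. Ribosome biogenesis and cytosolic ribosomal proteins each had 0.404, endoplasmic reticulum stress and cytosolic heat shock each 0.368, NF-kB and inflammation 0.306, cholesterol synthesis 0.601 and the oestrogen and tamoxifen response 0.858. Without KO replicate 1, lists called lower in KO included fatty acid oxidation and the TCA cycle (0.0153), ribosome biogenesis (0.0125) and endoplasmic reticulum stress (0.0469). Without the library labelled WT replicate 2, endoplasmic reticulum stress was called lower (0.00122) and NF-kB and inflammation higher (0.0362). Both lists set WT replicates 1 and 3 and KO replicate 1 apart from the other libraries. Mean log2 CPM was 7.29, 6.60 and 7.23 in WT and 7.24, 6.86 and 6.79 in KO for endoplasmic reticulum stress. For NF-kB and inflammation it was 2.65, 2.96 and 1.98 in WT and 2.32, 3.19 and 3.41 in KO. In each list of this paragraph, 0 members were called over all genes and 0 adjusted over the list alone.

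**Figure D2:**
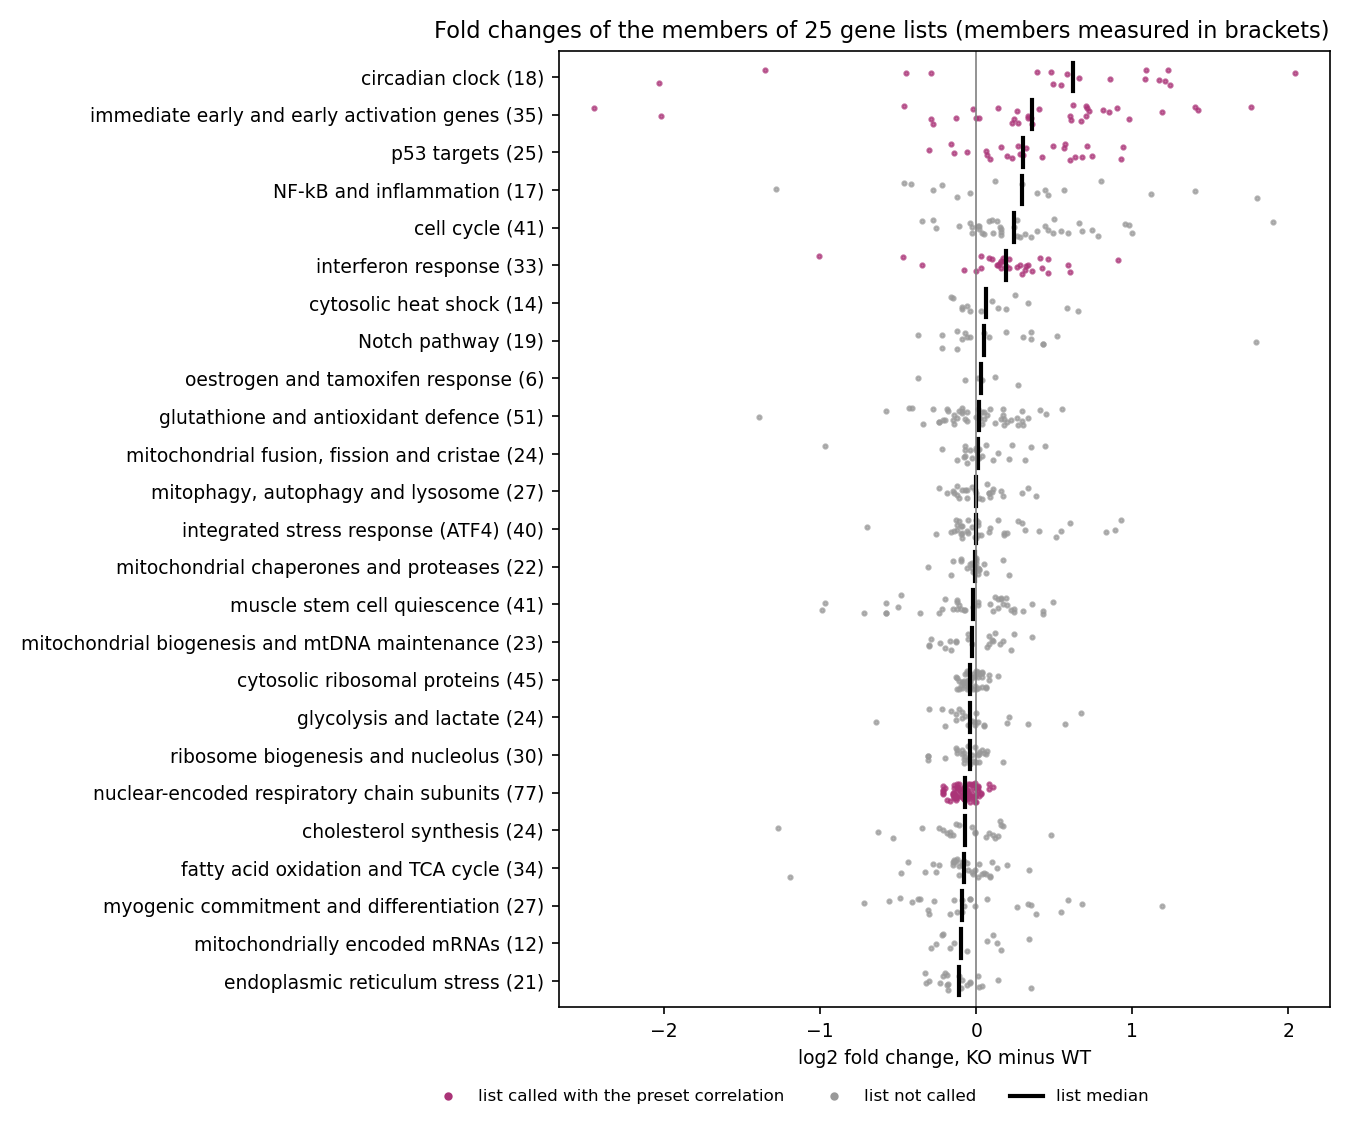
Log2 fold change (KO minus WT, horizontal axis) of each measured member (points) of 25 gene lists (vertical axis, number of members in brackets), with the median as a black bar and colour for the 5 lists called with the preset correlation. Medians run from 0.62 for the circadian clock to -0.11 for endoplasmic reticulum stress, and with an estimated correlation 0 lists were called.

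Cell cycle genes differed within each genotype. The list's mean log2 CPM was 4.81 and 4.29 in WT replicates 1 and 3, 2.09 in the library labelled WT replicate 2, 5.70 in KO replicate 1, and 2.62 and 2.51 in KO replicates 2 and 3. Mki67, a marker of cycling cells, was at 34.3, 1.59 and 38.1 CPM in WT and 78.7, 3.18 and 0.652 CPM in KO, and its log2 fold change of 0.16 (SE 1.63) fell to -3.70 without KO replicate 1. Between the genotypes the list was not called (adjusted p 0.956); its median (0.24) and mean (0.31) log2 fold change were positive while the test direction was down. With the preset correlation it was called lower in KO without KO replicate 1 (4.78e-07) and without the library labelled WT replicate 2 (0.00543), and higher with the surrogate variable (0.00057).

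Markers of other cell types of muscle were not called in any of the 8 lists, at adjusted p 0.609 for endothelial, 0.761 for fibro-adipogenic, 0.571 for leukocyte, 0.571 for mature fibre, 0.609 for smooth muscle and pericyte, 0.571 for Schwann cell, 0.571 for tenocyte and 0.26 for erythroid genes. Without WT replicate 3, mature fibre (0.0315) and endothelial markers (0.00442) were called lower in KO, as were erythroid genes without the library labelled WT replicate 2 (0.0365) or with the replicate block (0.00442). The excluded surface genes were low, Pecam1 at 14.7 ± 7.95 in WT and 11.5 ± 9.66 CPM in KO, Ly6a at 10.6 ± 5.17 and 10.4 ± 7.69, and Ptprc at 0.112 ± 0.194 and 0.393 ± 0.346. Hbb-bs of red cells was at 19.1 CPM in KO replicate 2 and 230 CPM in WT replicate 1. Endothelial markers had a test direction up with a median of -0.14, and fibro-adipogenic markers a direction down with a median of 0.09. Gsn, Col3a1, Chodl and Ncam1, on the fibro-adipogenic, tenocyte and Schwann lists, were at 596 CPM or more in every library.

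**Figure D3:**
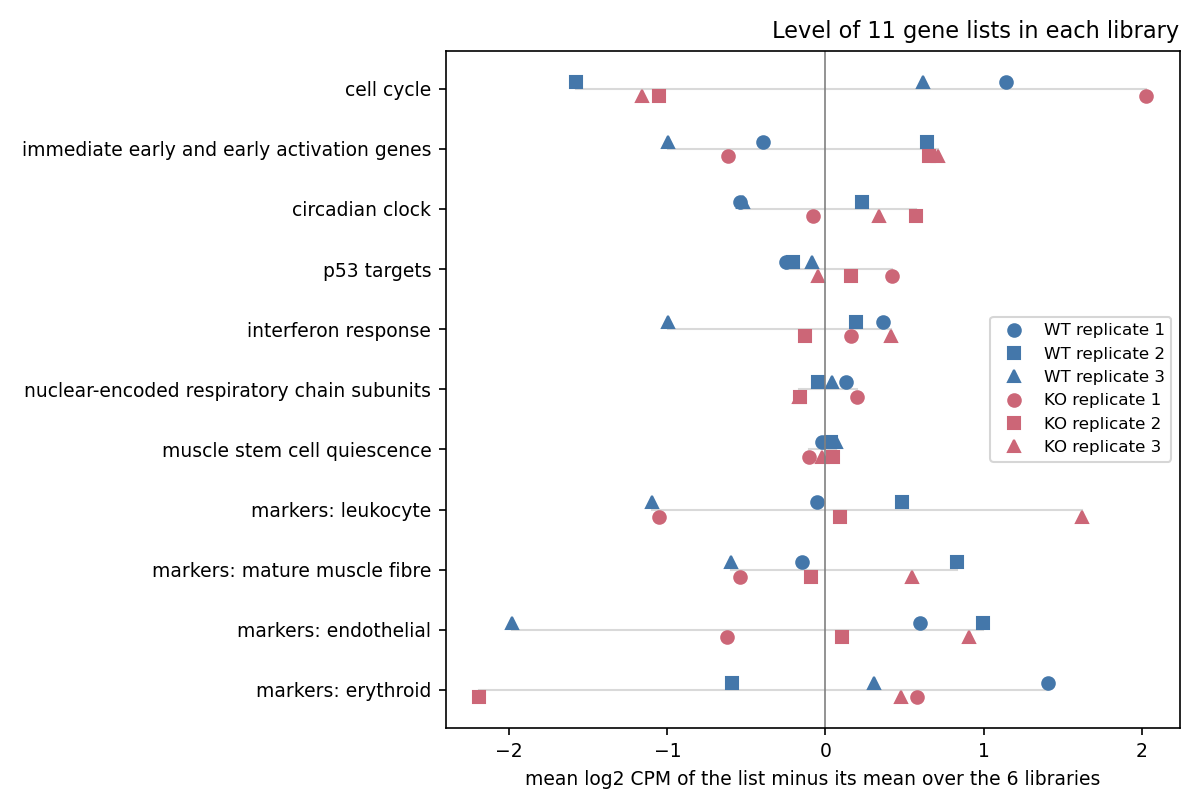
Mean log2 CPM of 11 gene lists in each library minus its mean over the 6 libraries (horizontal axis), with colour for genotype and symbol for replicate number. Cell cycle genes span 3.61 log2 units over the libraries and quiescence genes 0.17. p53 targets are the only list of the 11 with each KO library above each WT library, by 4.66 in KO replicate 3 against 4.62 in WT replicate 3. For any 1 list, chance separates the groups in either direction with a share of 10%.

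Sex-linked transcripts differed between libraries of 1 genotype. Xist, expressed from the inactive X in females, was at 355, 0.0209 and 508 CPM in WT and 401, 393 and 244 CPM in KO. Ddx3y, on the Y chromosome, was at 0.0354, 226 and 23.3 CPM in WT and 0.141, 22.9 and 90.2 CPM in KO. The library labelled WT replicate 2 thus had Ddx3y without Xist, WT replicate 1 and KO replicate 1 had Xist with Ddx3y near 0, and the other 3 libraries had both.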

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

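The surrogate variable, the Y-linked covariate and the genes named outside the rule were chosen after the data were seen, the other alternatives before. By edgeR, 0 genes were called under each alternative run with it and with each library left out. Limma voom was run once, with all 6 libraries, and called 0. DESeq2, run likewise, called 20 (11 higher, 9 lower), and the cause was not tested. Genes at an unadjusted p under 0.05 numbered 393, and 864 without the filter, 245 for protein-coding nuclear genes, 598 with the Y-linked covariate, and 324 to 818 with a library left out. Opa1 kept a negative log2 fold change throughout, from -1.38 to -0.87 with a library left out. Pathway lists called numbered 5, and 0 with an estimated correlation or with fry. With a library left out they ranged from 1 to 8 (8 without the library labelled WT replicate 2). The marker lists called ranged from 0 to 2. Of 65 values of the 5 called lists, 25 lost the call, and 13 of the values of uncalled lists gained one. Median shifts of all genes stayed under 0.1 in each setting.

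Whether replicate numbers pair the libraries was not settled. Same-number deviations correlated at 0.245, 0.105 and -0.072 and different-number ones at -0.285 to 0.207, and not every library correlated best with its own number. So few libraries cannot exclude a pairing. With the replicate block 0 genes were called (515 at an unadjusted p under 0.05), Opa1 was at -1.07, 5 pathway lists were called, and 1 marker list was, the erythroid one (adjusted p 0.00442). Myog was at -0.19, Mki67 at -0.47 and Dnm1l at 0, and the glycolysis list turned direction (0.948). With GC offsets and the replicate block, Myog was at -0.23, Mki67 at -0.49, Dnm1l at -0.01 and Eng at -0.02.

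Of 2137 gene values under alternatives, 77 in 30 genes changed sign or rounded to 0, 0 of them called. With limma voom, Cd68 was at 0.01, Ddx3y at 0.37, Mki67 at -1.36 and Myog at -0.36. Dnm1l was at -0.01 with upper-quartile scaling, without the filter and with the Y-linked covariate. Eng was at 0 with upper-quartile scaling, -0.01 without the filter and -0.02 with GC offsets. With the Y-linked covariate Myog was at -0.89 and Mki67 at -2.09, and with the surrogate variable Vcam1 was at 0.05 and Mfn1 at -0.07. With a library left out, log2 fold changes ranged from -0.74 to 0.55 for Acta1, -1.13 to 0.07 for Acta2, -0.48 to 3.23 for Ccne1, -0.28 to 0.46 for Cd68, -0.42 to 0.73 for Cd74 and -0.52 to 0.11 for Chodl. They ranged from -2.86 to 1.69 for Ddx3y, -0.20 to 0.18 for Dnm1l, -0.19 to 0.36 for Eng, -0.74 to 0.50 for Fabp4, -0.76 to 0.18 for Hba-a1, -1.05 to 0.16 for Hbb-bs and -0.12 to 0.61 for Itga7. The ranges were -0.81 to 0.32 for Ly6a, -0.08 to 0.58 for Mcm4, -0.12 to 0.26 for Mfn1, -0.26 to 0.27 for Mfn2, -3.70 to 0.73 for Mki67, -0.04 to 0.83 for Myod1, -2.12 to 0.62 for Myog, -0.17 to 0.09 for Ncam1 and -0.02 to 0.30 for Pax7. Pecam1 ranged from -1.30 to 0.04, Pmp22 from -0.12 to 0.35, Rara from -0.22 to 0.79, Spry1 from -0.26 to 0.10, Vcam1 from -0.14 to 0.06 and Xist from -0.32 to 0.96. For these changes of sign the cause was not tested. Of 102 genes followed besides Opa1, 61 kept their sign and moved by over 1.5 times in at least 1 such fit.

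Of 429 list values, 47 in 23 lists changed direction, and 3 of these were of a called list or called under the alternative. The cell cycle list was called higher in KO with the surrogate variable (adjusted p 0.00057) and was at 0.974 with fry. Mitophagy, autophagy and lysosome genes were at 0.967 with RLE scaling, glycolysis at 0.934 with the Y-linked covariate, endothelial markers at 0.918 with the surrogate variable and fibro-adipogenic markers at 0.998 with fry. With a library left out, adjusted p ranged from 8.4e-06 to 0.632 for interferon, 4.78e-07 to 0.656 for cell cycle, 0.394 to 0.825 for myogenic commitment, 0.292 to 0.738 for the integrated stress response and 0.163 to 0.937 for mitochondrial chaperones. It ranged from 0.171 to 0.768 for mitochondrially encoded mRNAs, 0.748 to 0.950 for fusion and fission, 0.616 to 0.951 for biogenesis, 0.632 to 0.995 for mitophagy, 0.416 to 0.995 for glutathione and 0.401 to 0.943 for glycolysis. For ribosome biogenesis it was 0.0125 to 0.937, ribosomal proteins 0.0966 to 0.995, endoplasmic reticulum stress 0.00122 to 0.995 and cholesterol synthesis 0.0522 to 0.937. Marker lists ranged from 0.00442 to 0.623 (endothelial, called lower in KO without WT replicate 3), 0.371 to 0.861 (fibro-adipogenic), 0.103 to 0.888 (leukocyte), 0.0315 to 0.861 (fibre), 0.0868 to 0.861 (smooth muscle), 0.0534 to 0.623 (Schwann), 0.322 to 0.861 (tenocyte) and 0.0365 to 0.817 (erythroid). The cause was not tested. Thinning to the smallest total left 0 genes called by edgeR (383 at an unadjusted p under 0.05), a count that could not fall; it matched the gene totals and no other property of the libraries.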

Other observations

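The gene-count splits, the tests of a swap, a wrong label, the sexes and library quality, the positions near Opa1 and Pax7, and the reading of the clock test from the Arntl-phase genes alone were chosen after the results were seen. Genes called only by DESeq2 at low levels included Klhdc7a (1.97 ± 1.91 CPM in KO, 0.00696 ± 0.012 in WT) and Colgalt2 (1.13 ± 0.892 CPM in KO, 0 in each WT library). Syt14 was at 0.804 ± 0.451 CPM in WT and 0 in each KO library. Genes at 0 counts in 3 libraries and above 0.5 CPM in each of the other 3 numbered 0 between the genotypes and up to 11 in the 9 other splits. These limits leave out the genes just named, so the count decides nothing about them. Colgalt2 was at 0.482 CPM in KO replicate 1, Syt14 at 0.407 CPM in WT replicate 1, and Klhdc7a at 0.0209 CPM in the library labelled WT replicate 2. With 0 genes called, the planned position test could not be run; within 10 Mb of Opa1, 1.06% of genes had an unadjusted p under 0.05 in edgeR against 2.09% elsewhere, and within 10 Mb of Pax7 3.05% against 2.08% (Fisher's exact p = 0.445 and 0.27).

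The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes, which all 10 splits match or exceed by necessity, so this count decides nothing, and the highest other called 39. That split set WT replicates 1 and 3 with KO replicate 1 against the library labelled WT replicate 2 with KO replicates 2 and 3. It had 2508 genes at an unadjusted p under 0.05 in edgeR against 393 in the real one. Picked as the highest of the 10, it describes a division of the libraries other than genotype and does not test it. For pathway lists the real split called 5 and the highest other 11, with 6 of 10 splits at least as high. A camera p as small was given by 5 of 10 splits for immediate early genes (real 0.000623, smallest other 1.29e-16), 4 for respiratory chain subunits (0.00125, 1.23e-11) and 6 for interferon genes (0.00104, 2.7e-10). For p53 targets (0.000405, 0.00467) and the circadian clock (2.1e-05, 0.000122) it was 1 of 10, the real split itself.

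Opa1 of the library labelled WT replicate 2 (31.4 CPM) lay within the KO range. A swap with a KO library is argued against, since the highest KO value was 0.5 times the lower of the other 2 WT values. Loss of long transcripts is argued against too: 1732 genes of similar length and level had a median log2 ratio to the other 2 WT libraries of 0.04 (95% interval 0.02 to 0.06), against -1.12 for Opa1. A single wrong label or KO cells in this library cannot be told apart from a low WT value, since its deviation from WT correlated across genes with that of the KO libraries at 0.1, and KO libraries left out in turn gave -0.12, 0.02 and 0.01. These values leave open that the library may hold cells with recombined Opa1. Xist was at 0.0209 CPM in this library and at 401, 393 and 244 CPM in KO replicates 1 to 3. That argues against material mixed in from those KO libraries. A wrong label or KO cells of male animals alone stay open.

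Cell cycle genes were high in WT replicates 1 and 3 and KO replicate 1, and low in the library labelled WT replicate 2 and KO replicates 2 and 3. One candidate explanation is different shares of male and female animals: over the 6 libraries the cell cycle mean correlated with the Y-linked sum at r = -0.91 (exact permutation p = 0.00417, adjusted p = 0.0417 over 10 relations; rho = -0.94, exact p = 0.0167; r = -0.76 without the 2 farthest libraries). This met the limit set for the test, but both measures fall into clusters, which was taken into account only after r was seen and leaves the correlation unable to decide, and 2 libraries whose Y-linked sums differed by 1.25 times differed by 1.67 log2 units in the cell cycle mean. Library quality stays open in the same way: the cell cycle mean correlated with the share of reads without a feature at r = -0.91 too (exact p = 0.00972, adjusted p = 0.0486; rho = -0.89, exact p = 0.0333; r = -0.79 without the 2 farthest libraries), which falls into clusters as well. That share (11.15%, 14.64% and 11.57% against 16.27%, 15.45% and 17.02%), immediate early genes (mean log2 CPM 5.87, 5.27 and 5.65 against 6.91, 6.92 and 6.98) and mitochondrially encoded mRNAs (6.93, 6.89 and 6.73 against 7.59, 7.37 and 7.21) were all lower in the 3 libraries with high cell cycle genes, so the sexes and library quality cannot be told apart here. Cells of another type, which the sort would remove, stay open as well. The largest positive r among 8 marker lists, the sign that cycling cells of another type would give, was 0.62 (erythroid, exact p = 0.188, adjusted p = 0.269; rho = 0.66, exact p = 0.175; r = 0.66 without the 2 farthest libraries). Larger in size were the negative r of mature fibre (-0.82, exact p = 0.0625; rho = -0.83, exact p = 0.0583; r = -0.59 without the 2 farthest libraries), leukocyte (-0.75, exact p = 0.0986), smooth muscle (-0.74, exact p = 0.126) and tenocyte markers (-0.64, exact p = 0.103), at adjusted p of 0.206 to 0.21. Without the 2 farthest libraries r was -0.88 for leukocyte, -0.39 for smooth muscle and 0.55 for tenocyte markers, so the tenocyte sign rests on those libraries, and fibro-adipogenic markers moved from 0.32 (exact p = 0.522) to 0.84, above erythroid. The order of the lists thus depends on which libraries are kept. The clusters of the cell cycle mean limit all 8. No other explanation of the differences within a genotype was tested, and stem cells that had left quiescence remain possible. Myog was at 125, 169 and 276 CPM in WT replicates 1 and 3 and KO replicate 1. It was at 14.6, 24.4 and 22.8 CPM in the library labelled WT replicate 2 and KO replicates 2 and 3. Myod1 and the myogenic commitment list did not divide the libraries this way, both being lowest in WT replicate 3 (163 CPM and a mean log2 CPM of 4.09).

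Circadian clock genes rose as a list with the preset correlation, a call lost with an estimated correlation (adjusted p 0.983), with fry (0.974) and without WT replicate 1 (0.0935). For a different time of day of the sort, the pattern predicted was lower genes that peak with Arntl and higher genes that peak with Per and Dbp. Other shifts of the hour could give other patterns. The mean log2 difference of 10 Per and Dbp-phase genes was 1.15 (SE 0.39, exact p = 0.1, the smallest possible), but these 10 of the list's 18 measured members carry the rise that prompted the test, so they restate it. The 5 Arntl-phase genes are the part left to decide. Their mean log2 difference was -0.84 (SE 0.55, exact p = 0.2), less than 2 SE from 0, and -0.37 without KO replicate 1, whose mean log2 CPM was 3.02 against 4.41 and 4.47 in the other KO libraries and 4.46, 4.62 and 5.36 in WT. Cry1 (log2 fold change 0.66) went the other way. The gap between both sets was 1.99 (SE 0.77, exact p = 0.1, the smallest possible), at 1.93 to 3.58 in KO and -0.46 to 1.56 in WT, and 1.44 to 2.45 with a library left out. Of this gap, 1.15 comes from the Per and Dbp-phase genes, so it does not decide either. A shift in clock phase between the groups thus cannot be told apart from no shift by these values. The hour of collection, which the labels do not give, and an effect of Opa1 loss on the clock both stay open. So does the division of the libraries seen for cell cycle genes. The whole list's mean log2 CPM followed it, at 5.00, 5.02 and 5.46 against 5.77, 6.11 and 5.88. The 10 Per and Dbp-phase genes did not, at 6.60 in KO replicate 1 and 6.17 in the library labelled WT replicate 2.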
